A study of Mus musculus with 36 samples.

How the data were processed

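Bulk RNA sequencing was used on tumor, kidney, lung, liver, skeletal muscle and heart of MC38 tumor-bearing mice given ICB or IgG, with 3 libraries per tissue and treatment and 36 in all. Per the labels, RNA came from flash-frozen tissue. The deposited table holds FPKM values made by the authors for 18781 rows named by gene symbol. FPKM are fragments per kilobase of gene, scaled here to the reads of a library times a normalization factor that the values imply. Per the submitters' processing notes the reads were aligned with HISAT2 2.1.0 to mm10, and edgeR is among the tools named. The counter, the annotation, the strandedness and the edgeR version are not given in the sources used here.

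Whole read numbers were recovered from the FPKM values for 18781 of 18781 rows (tolerance 0.001 reads). They gave 19005189 to 25512980 reads per library, and normalization factors of 0.532 to 1.595 were implied by the FPKM scaling, differing within a tissue by at most a ratio of 1.22. The 15 rows without a name (0.0834% to 0.374% of the reads) and 3 symbols shared by 2 rows each were left out. Gene positions come from GENCODE M21, and 3 list symbols were matched under a newer name. No library was a duplicate of another of its group (36 pairs compared).

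Within each tissue, log2(FPKM + 1) was compared between 3 ICB and 3 IgG libraries with limma (moderated test with a mean-variance trend, two-sided), for genes with FPKM of at least 1 in at least 3 of the 6 libraries. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A set of 45 gene lists was tested with camera (preset correlation 0.01), adjusted over the lists of a tissue with at least 5 tested members, and again with an estimated correlation. For the comparison of tissues and the average of the 5 organs, all 36 libraries were fitted with 12 group means. The average used genes passing the filter in each organ, the comparison those passing in at least 1 tissue. The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, except for the list test on the organ average and the additions named here.

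The rule named, per tissue, passing genes with separate groups (the 10 largest differences each way) or, with fewer than 10 passing, the 5 smallest p-values each way, passing over predicted genes, up to 4 members of each described list, and Pdcd1, Ctla4, Cd274, Cd8a, Foxp3, Ifng and Cxcl9. For the organ average and the tumor against the organs it named the 10 smallest p-values each way. Not every gene that meets the rule is printed. Gm2606 and the sequence copies of kidney genes, and Isg15 and Cxcl10 in the plot of tumor genes, were chosen after their values were seen, as was Adipoq in the tumor. The granzyme genes Gzmd, Gzme and Gzmf in the plot of tumor genes belong to no list and lie outside the rule as well.

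Alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization, TPM scale, no trend, array weights, 1 fit of all 36 libraries, a minimum absolute log2 difference of 1, fry, the title number as a replicate block, and leaving out each library or organ. Limma-voom on the recovered reads, the filter in all 6 tissues, leaving out single libraries in the 36-library fits, the list test on the organ average with its estimated correlation and fry, and the exact test per title number were added after the data were seen. The procedure was tested on simulated data, after it had run on the real data and with a noise model replaced after its first output was seen, with 50 changed genes per tissue and effect size. It recovered 0 to 23 genes at a log2 difference of 0.5, 20 to 43 at 1 and 45 to 50 at 2, with 4 to 10 false calls. All 200 changed genes of a tissue were simulated together, only among more highly expressed genes and with noise independent between genes. The real tissues had few passing genes, so these counts may overstate the recovery there. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and Biopython 1.88.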

Results

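Gene expression was measured by bulk RNA sequencing in 36 libraries from C57BL/6 mice carrying MC38 tumors, which grow from a mouse colon carcinoma line. The animals had received antibodies against PD-1 and CTLA-4, receptors that restrain T cells, at a high dose (immune checkpoint blockade, ICB), or control IgG. Tumor, kidney, lung, liver, skeletal muscle and heart were each represented by 3 ICB and 3 IgG libraries. The libraries held between 19005189 and 25512980 reads. Mitochondrial genes took 16.6% to 25.6% of the reads in heart and 1.58% to 3.24% in lung. Hemoglobin genes took a smaller share of the reads in every ICB library than in any IgG library of kidney (0.0181% to 0.0283% against 0.0405% to 0.0548%), heart (0.0266% to 0.0341% against 0.0473% to 0.255%) and muscle (0.0193% to 0.0519% against 0.0596% to 0.0939%). The shares overlapped in lung, liver and tumor. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

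The first question was which genes and which groups of functionally related genes differed between ICB and IgG in each tissue. Interferon-induced genes were higher with ICB in the tumor, markers of macrophages and MHC class II genes were higher in kidney, lung, liver and muscle, and erythroid genes were lower in kidney, lung, muscle and heart. Between 7 and 14 of the 29 to 38 testable gene lists were called in a tissue by camera, the competitive list test of limma, with its preset correlation between genes. With an estimated correlation 0 lists were called in any tissue, and the self-contained test fry called 1 list in the tumor and 0 elsewhere. No list member passed over all genes tested in its tissue. Of the 10 ways to split a tissue's 6 libraries 3 against 3, the highest count in a split other than the real one was 17 lists in tumor, 19 in kidney, 21 in lung, 14 in liver, 16 in muscle and 13 in heart. With 3 libraries against 3, an exact permutation test of a list's mean value cannot give a two-sided p below 0.1.

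**Figure D1:**
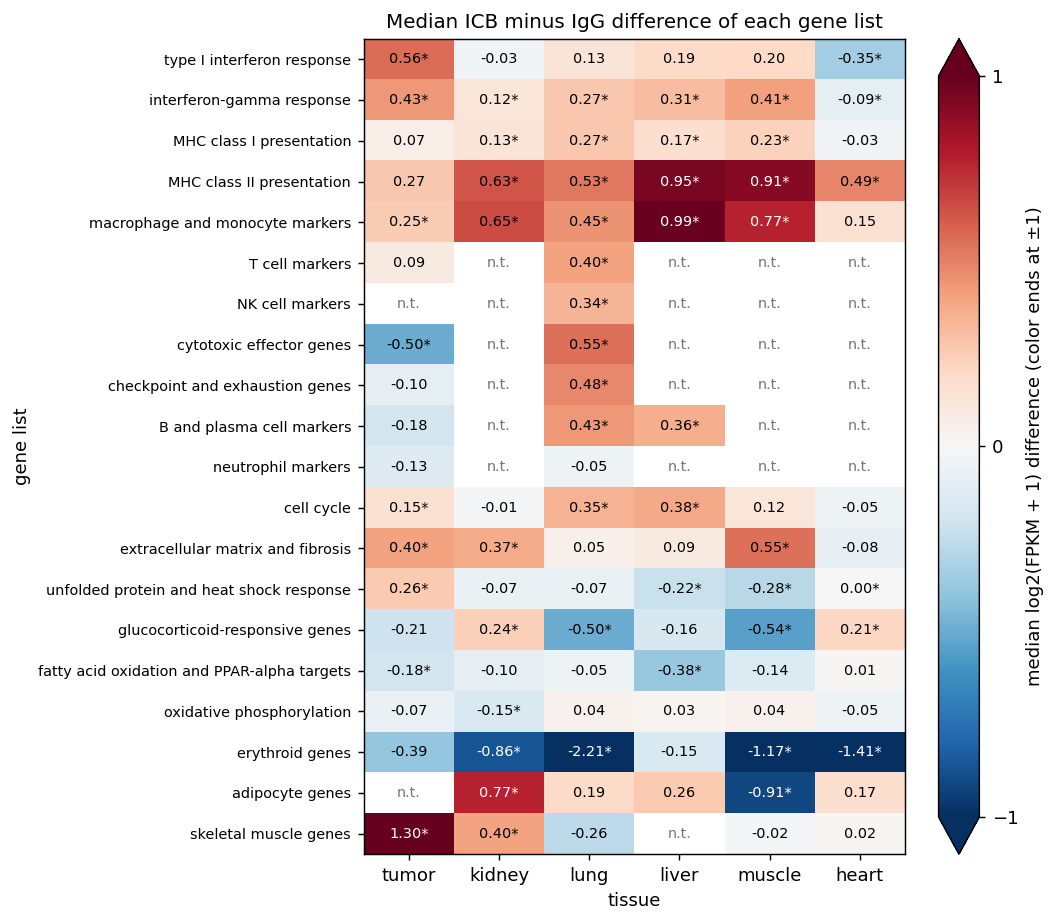
Median log2(FPKM + 1) difference, ICB minus IgG, over the tested members of 20 gene lists (vertical axis) in 6 tissues (horizontal axis), with 3 libraries per group; red is higher in ICB, blue is lower, an asterisk marks a camera adjusted p under 0.05 with the preset correlation, and n.t. marks lists with fewer than 5 tested members. Macrophage and monocyte markers reach medians of 0.65 in kidney, 0.99 in liver and 0.77 in muscle, and erythroid genes -2.21 in lung.

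In the tumor, genes induced by interferons were higher with ICB and genes of cytotoxic lymphocytes were lower. All 26 tested members of the type I interferon response were higher (median log2 difference 0.56). Among them were Ifit1, an inhibitor of viral translation (log2 difference 0.92 ± 0.20, SE, n = 3 per group, as for all differences within a tissue), Zbp1, a sensor of foreign nucleic acid (0.75 ± 0.19), and Ifi44 (0.82 ± 0.22). The list had a camera adjusted p = 4.78e-18, 8 members passed adjusted over the list alone, and it had an adjusted p = 0.546 with an estimated correlation. Of the 31 tested interferon-gamma response genes 28 were higher (median 0.43, camera adjusted p = 3.09e-17), and 13 passed adjusted over the list alone, with an adjusted p = 0.446 with an estimated correlation. Their leading members were the interferon-inducible GTPases Gbp3 (0.92 ± 0.12, from 20.4 ± 1.36 to 39.4 ± 4.37 FPKM, mean ± SD; chromosome 3, 142560026 to 142573209), Tgtp2 (0.90 ± 0.13) and Igtp (0.84 ± 0.13), each higher in all 3 ICB libraries than in any IgG library.

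Of the 11 tested cytotoxic effector genes, which encode the proteases and the pore-forming protein that lymphocytes release onto target cells and related receptors, 10 were lower in the ICB tumors (median -0.50, camera adjusted p = 0.000227), with an adjusted p = 0.627 with an estimated correlation. Gzmc (-1.76 ± 0.47) and Gzma (-0.61 ± 0.16) were lower in all 3 ICB libraries, and were the 2 members that passed adjusted over the list alone. Gzmb (-1.16 ± 0.43) and the perforin gene Prf1 (-1.31 ± 0.52) overlapped between the groups. ICB replicate 1 stood at 26.3 and 16.95 FPKM for these genes, above the 22.1 and 13.5 FPKM of IgG replicate 3. T cell markers had a median of 0.09 (6 of 8 tested markers higher, camera adjusted p = 0.479), and all 4 tested NK cell markers were lower (median -0.39), too few for a list test. The NK list shares Gzma, Prf1 and Eomes with the cytotoxic list, and the tested NK markers included Gzma and Prf1. The NK markers are thus not separate evidence. Checkpoint and exhaustion genes had a median of -0.10 (9 tested, adjusted p = 0.616), B and plasma cell markers -0.18 (5 tested, adjusted p = 0.661), neutrophil markers -0.13 (6 tested, adjusted p = 0.686) and dendritic cell markers 0.07 (5 tested, adjusted p = 0.435).

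**Figure D2:**
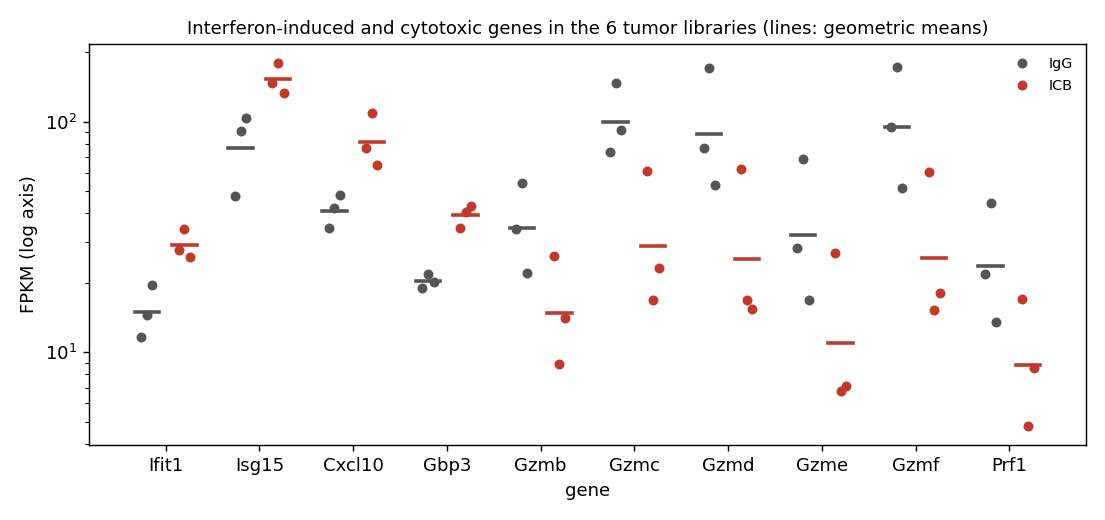
FPKM on a log axis (vertical) of interferon-induced and cytotoxic genes (horizontal) in the 3 IgG (gray) and 3 ICB (red) tumor libraries, each point 1 library and each line a geometric mean. Ifit1, Isg15, Cxcl10 and Gbp3 separate the groups, with Cxcl10 at 34.5 to 48.0 FPKM in IgG and 65.1 to 109 FPKM in ICB, while Gzmb ranges over 22.1 to 54.2 FPKM in IgG and 8.86 to 26.3 FPKM in ICB.

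Another tumor list called in the higher direction was the unfolded protein and heat shock response (14 of 17 higher, median 0.26, camera adjusted p = 1.86e-05), with the stress-induced genes Trib3 (0.70 ± 0.20) and Atf4 (0.36 ± 0.11). The cell cycle list was higher as well (22 of 25 higher, median 0.15, adjusted p = 8.03e-05), with the proliferation genes Foxm1 (0.35 ± 0.12) and Mki67 (0.28 ± 0.10). These had an adjusted p = 0.215 and an adjusted p = 0.671 with an estimated correlation, and fry called the former (adjusted p = 0.0263). Extracellular matrix genes (18 of 22 higher, median 0.40, adjusted p = 0.0052, and adjusted p = 0.627 with an estimated correlation) included the protease inhibitor Timp1 (0.43 ± 0.10) and the collagen Col1a2 (1.29 ± 0.56). Macrophage and monocyte markers (13 of 18 higher, median 0.25, adjusted p = 0.013, and adjusted p = 0.671 with an estimated correlation) included the monocyte genes Ly6c2 (1.50 ± 0.33) and Ccr2 (0.65 ± 0.18). Hypoxia and glycolysis genes (17 of 19 higher, median 0.20, adjusted p = 0.0232, and adjusted p = 0.714 with an estimated correlation) were called. Fatty acid synthesis genes (10 of 13 higher, median 0.18, adjusted p = 0.0232, and adjusted p = 0.627 with an estimated correlation) were also called. Fatty acid oxidation genes were lower (11 of 13, median -0.18, adjusted p = 0.0052, and adjusted p = 0.419 with an estimated correlation). Among them was Cpt1a, which carries fatty acids into mitochondria (-0.44 ± 0.14). None of these lists had a member passing adjusted over the list alone. Some calls depended on 1 library. Macrophage markers lost the call (adjusted p = 0.170 without IgG replicate 1, 0.135 without IgG replicate 2, 0.0637 without ICB replicate 3). Extracellular matrix lost the call (0.204 without IgG replicate 2). Fatty acid oxidation lost the call (0.0735 without IgG replicate 1). Hypoxia and glycolysis lost the call (0.709 in the opposite direction without IgG replicate 3, 0.180 without ICB replicate 1 and without ICB replicate 3). Fatty acid synthesis lost the call (0.678 without IgG replicate 3, 0.156 without ICB replicate 1). The cell cycle kept its call, but its difference in mean list value fell from 0.15 to 0.08 without IgG replicate 1. Of the called tumor lists, the mean value per library separated the groups only for the 2 interferon lists, the unfolded protein response, fatty acid oxidation, fatty acid synthesis and muscle atrophy genes.

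Skeletal muscle transcripts also differed between the tumor libraries. All 6 tested skeletal muscle genes were higher in ICB (median 1.30, camera adjusted p = 0.0154, and adjusted p = 0.671 with an estimated correlation). The mean list value was 5.27 in ICB replicate 2, with a lowest value of 1.24 in the other ICB libraries and with 1.37 to 1.77 in IgG. The actin gene Acta1 stood at 180 FPKM in that library and at 1.21 to 8.30 FPKM in the other 5, and the list was no longer called without it (adjusted p = 0.469) or without IgG replicate 3 (adjusted p = 0.132). The muscle atrophy and regeneration list (8 of 9 higher, median 0.26, adjusted p = 0.0393, and adjusted p = 0.627 with an estimated correlation) was called. It lost the call without any of 5 of the 6 libraries (adjusted p = 0.0615 without IgG replicate 2, 0.295 without IgG replicate 3, 0.0782, 0.0548 and 0.0576 without ICB replicates 1, 2 and 3). Neither list had a member passing adjusted over the list alone. Only 3 adipocyte genes were tested in the tumor, too few for a list test (median 0.32). The fat gene Adipoq, looked at after the data were seen, stood at 3.15 and 3.99 FPKM in ICB replicates 2 and 3, at 0.211 FPKM in ICB replicate 1 and at 0 to 0.0436 FPKM in IgG. The higher extracellular matrix genes thus stood beside higher muscle and fat transcripts.

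No single gene passed in the tumor with limma (0 of 11398 tested). There 783 had an unadjusted p under 0.05 against 570 by chance, and limma-voom on the recovered reads called 0. The groups did not overlap for 13.1% of the genes, where chance gives 10%. Besides those named, the smallest p-values belonged upward to Ifi206 (1.16 ± 0.19) and the receptor gene Klra2 (0.71 ± 0.13). Downward they belonged to Mir7-1 (-0.96 ± 0.14), a microRNA gene inside Hnrnpk, the polymerase gene Polm (-0.60 ± 0.12), Mylip (-0.65 ± 0.13), Firre (-0.59 ± 0.12) and Bmyc (-0.57 ± 0.11). The chemokine Cxcl9, which attracts T cells, stood at 6.45 ± 3.03 FPKM in IgG and 12.3 ± 2.02 FPKM in ICB (log2 difference 0.91 ± 0.28, adjusted p = 0.697). Pdcd1, which encodes PD-1 (0.21 ± 0.25), and Cd274, which encodes its ligand (0.25 ± 0.26), changed sign without IgG replicate 3 (-0.06 and -0.04). Cd8a, Ctla4 and Foxp3 lay under the expression filter in the tumor, and Ifng is not analysed here in any tissue. Without IgG replicate 3 limma called 6 tumor genes and without ICB replicate 1 it called 1, while 1 fit of all 36 libraries, which shares the spread between tissues, called 69.

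In the kidney, transcripts of macrophages, of MHC class II antigen presentation and of extracellular matrix were higher with ICB, and erythroid transcripts were lower. All 13 tested macrophage and monocyte markers were higher (median 0.65, camera adjusted p = 5.14e-12, and adjusted p = 0.312 with an estimated correlation), and 5 passed adjusted over the list alone. Mpeg1, a pore-forming protein of macrophages, stood at 4.01 ± 1.01 FPKM in IgG and 9.69 ± 2.51 FPKM in ICB (1.08 ± 0.20). The complement gene C1qa (0.97 ± 0.26), the chemokine receptor gene Cx3cr1 (0.61 ± 0.18) and Cd68 (0.94 ± 0.29) lay higher in every ICB library. All 7 tested MHC class II genes were higher (median 0.63, adjusted p = 7.3e-08, and adjusted p = 0.312 with an estimated correlation). Leading were the invariant chain Cd74 (0.91 ± 0.22), the 1 member that passed adjusted over the list alone, and H2-Ab1 (0.68 ± 0.23). All 19 extracellular matrix genes were higher (median 0.37, adjusted p = 3.95e-12, and adjusted p = 0.312 with an estimated correlation), among them the collagens Col6a1 (0.57 ± 0.17) and Col1a1 (0.83 ± 0.33), and 0 passed adjusted over the list alone.

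All 8 tested erythroid genes were lower in the ICB kidneys (median -0.86, camera adjusted p = 6.14e-09, and adjusted p = 0.312 with an estimated correlation). Of these 4 passed adjusted over the list alone, namely the hemoglobin genes Hbb-bs (-1.14 ± 0.18), Hba-a1 (-1.01 ± 0.22) and Hbb-bt (-1.21 ± 0.27) and the heme synthesis gene Alas2 (-0.80 ± 0.19). Adipocyte genes were higher in the same comparison (12 of 12, 0 passing adjusted over the list alone, median 0.77, adjusted p = 6.25e-08, and adjusted p = 0.471 with an estimated correlation). Members included Ucp1, the uncoupling protein of brown fat, at 1.23 to 8.80 FPKM in IgG and 9.11 to 39.1 FPKM in ICB. Skeletal muscle genes were higher too (5 of 6, median 0.40, adjusted p = 0.000143, and adjusted p = 0.312 with an estimated correlation). Of them 3, Atp2a1 (0.58 ± 0.10), Acta1 (0.93 ± 0.18) and Tnnt3 (0.57 ± 0.16), passed adjusted over the list alone. Atp2a1 lay near the filter, at 0.5865 FPKM in IgG and 1.37 FPKM in ICB on average. The macrophage, MHC class II and matrix differences in kidney stood beside higher fat and muscle transcripts.

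Immediate early genes, which respond within minutes to stimuli, were higher in the ICB kidneys (11 of 13, median 0.31, camera adjusted p = 2.87e-06, and adjusted p = 0.312 with an estimated correlation), led by Nr4a1 (0.77 ± 0.24). Genes of activated endothelium were higher (8 of 9, median 0.18, adjusted p = 0.00204, and adjusted p = 0.312 with an estimated correlation), led by Pecam1 (0.34 ± 0.13). Interferon-gamma response genes (18 of 21 higher, median 0.12, adjusted p = 0.000484), MHC class I genes (15 of 18, median 0.13, adjusted p = 0.000666), glucocorticoid-responsive genes (12 of 15, median 0.24, adjusted p = 0.00132) and acute phase genes (10 of 11, median 0.33, adjusted p = 0.00139) were called higher, each with an adjusted p = 0.586 with an estimated correlation. They included the GTPase Gbp2 (0.46 ± 0.17), the class I gene H2-K1 (0.38 ± 0.19), Ddit4 (0.62 ± 0.17) and the lipopolysaccharide-binding protein Lbp (0.35 ± 0.14). Cholesterol synthesis genes were lower (18 of 19, median -0.20, adjusted p = 2.29e-05, and adjusted p = 0.483 with an estimated correlation), with Cyp51 (-0.43 ± 0.15). Oxidative phosphorylation genes were lower too (23 of 24, median -0.15, adjusted p = 8.85e-05, and adjusted p = 0.586 with an estimated correlation), with Cox7a2 (-0.30 ± 0.14). None of these lists had a member passing adjusted over the list alone. Kidney tubule genes, which mark the organ's own epithelium (20 tested, median -0.05, adjusted p = 0.517), and kidney injury genes (7 tested, median 0.05, adjusted p = 0.127) were not called. Some calls depended on 1 library. Interferon-gamma response lost the call (adjusted p = 0.565 without IgG replicate 3, 0.281 without ICB replicate 3). MHC class I lost the call (0.454 and 0.281 without the same libraries). Acute phase lost the call (0.426 without IgG replicate 3, 0.704 without ICB replicate 1). Glucocorticoid-responsive genes lost the call (0.407 without IgG replicate 2, 0.704 without ICB replicate 1). Oxidative phosphorylation lost the call (0.0547 without IgG replicate 2). Cholesterol synthesis lost the call (0.0929 without ICB replicate 1). Other lists kept their calls, but without 1 library the difference in mean list value fell from 0.56 to 0.32 for MHC class II (ICB replicate 3) and from 0.82 to 0.46 for adipocyte genes (IgG replicate 3). It fell from 0.38 to 0.25 for extracellular matrix (IgG replicate 2), from 0.31 to 0.19 for skeletal muscle genes (IgG replicate 1) and from 0.16 to 0.10 for endothelium (ICB replicate 3). For macrophage markers it fell from 0.62 to 0.44 (ICB replicate 1). Of the called kidney lists, the mean value per library separated the groups only for macrophage, MHC class II, erythroid, cholesterol synthesis and skeletal muscle genes. The margin was narrow for macrophage and MHC class II genes. ICB replicate 2 stood at 2.35 and 4.27, against highest IgG values of 2.33 and 4.25. For skeletal muscle genes ICB replicate 3 stood at 1.95 against 1.92 in IgG replicate 2. Rescaling each library to a common sum (TPM scale) moved the medians to -0.04 for oxidative phosphorylation, -0.12 for cholesterol synthesis, 0.26 for interferon-gamma response and for MHC class I, 0.30 for endothelium, 0.52 for acute phase and 0.63 for skeletal muscle genes.

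Of 11901 kidney genes tested with limma 2 passed, both lower in ICB, where 441 had an unadjusted p under 0.05 against 595 by chance, and limma-voom on the recovered reads called 1. The mitochondrial gene mt-Nd3, a subunit of respiratory complex I (mitochondrial genome, 9459 to 9806), fell by 1.42 (SE 0.13, adjusted p = 0.0173), from 33.9 ± 1.73 to 12.1 ± 1.92 FPKM. Gm2606, a processed pseudogene at chromosome 15, 12574889 to 12575890, fell by 2.15 (adjusted p = 0.00272). It lies outside the naming rule and was named after its values were seen. Both have near-identical copies in the genome: mt-Nd3 matches the nuclear pseudogene Gm28438 with 0 mismatches, and Gm2606 matches Gapdh over 1002 bases with 1 mismatch. How reads shared by such copies were assigned is not given in the sources used here, and the copies themselves had log2 differences of -0.60 and 0.04. Gm28438 stood at 337 FPKM in IgG and 200 FPKM in ICB, well above mt-Nd3 itself. Whether the fall of mt-Nd3 was one of the mitochondrial transcript thus cannot be told. The mt-Nd3 difference stayed at -1.53 to -1.32 without each library in turn. Its call no longer passed without IgG replicates 1, 2 or 3 or ICB replicates 1 or 3 (adjusted p = 0.163, 0.0515, 0.167, 0.0733 and 0.148). The count was 1 gene without any of those libraries and 9 genes without ICB replicate 2. The cytochrome oxidase gene mt-Co3, which has the identical nuclear copy Gm28437, had a difference of -1.92 ± 0.40 (adjusted p = 0.992). The dendritic cell gene Itgax (0.69 ± 0.13) and the chemerin receptor gene Cmklr1 (0.56 ± 0.11) were among the smallest p-values upward. Itgax lay near the filter, at 0.526 FPKM in IgG and 1.45 FPKM in ICB on average. Cd274 had a difference of 0.13 ± 0.13. Pdcd1, Ctla4, Cd8a, Foxp3 and Cxcl9 lay under the filter. The groups did not overlap for 8.66% of the genes, where chance gives 10%.

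In the lung, transcripts of T cells, macrophages and proliferating cells were higher with ICB, and hemoglobin transcripts were lower by the largest margin of the 6 tissues. All 18 tested T cell markers were higher (median 0.40, camera adjusted p = 7.74e-09, and adjusted p = 0.780 with an estimated correlation), 0 passing adjusted over the list alone. Among them were the co-receptor Cd4 (0.50 ± 0.17) and the signaling kinases Lck (0.77 ± 0.32) and Zap70 (0.48 ± 0.18). All 7 checkpoint and exhaustion genes were higher (median 0.48, adjusted p = 5.94e-07, and adjusted p = 0.745 with an estimated correlation). The inhibitory receptors Tigit (0.65 ± 0.16), Lag3 (0.48 ± 0.12) and Havcr2 (0.49 ± 0.15) passed adjusted over the list alone. Macrophage and monocyte markers were higher (17 of 19, median 0.45, adjusted p = 8.85e-08, and adjusted p = 0.404 with an estimated correlation). Leading were the growth factor receptor Csf1r (1.00 ± 0.20), the 1 member that passed adjusted over the list alone, and C1qb (0.54 ± 0.16). All 14 cell cycle genes were higher (median 0.35, adjusted p = 7.06e-09, and adjusted p = 0.735 with an estimated correlation), and Mki67 (0.75 ± 0.15), Ccnb2 (0.88 ± 0.19) and Mcm5 (0.59 ± 0.14) passed adjusted over the list alone. All 8 erythroid genes were lower (median -2.21, adjusted p = 9.92e-09, and adjusted p = 0.780 with an estimated correlation). Members included Hba-a2 at -3.13 ± 0.84 and Alas2 at -2.05 ± 0.72, and 7 passed adjusted over the list alone. The mean list value was 8.09 and 7.62 in IgG replicates 1 and 2, but 5.51 in IgG replicate 3, within the 3.83 to 5.69 of ICB.

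Further lists were called higher in the lung, each with an adjusted p = 0.780 with an estimated correlation. These were cytotoxic effector genes (9 of 11, median 0.55, camera adjusted p = 0.00033), with Nkg7 (0.84 ± 0.37) and Klrg1 (0.51 ± 0.22), and NK cell markers (7 of 7, median 0.34, adjusted p = 0.00369), with Ncr1 (0.90 ± 0.38). They also comprised B and plasma cell markers (17 of 20, median 0.43, adjusted p = 0.000401), with the immunoglobulin constant region Ighg1 (2.90 ± 0.64), the 1 member that passed adjusted over the list alone, and MHC class II genes (10 of 10, median 0.53, adjusted p = 4.39e-05), with H2-Oa (0.75 ± 0.23). The last of them were MHC class I genes (18 of 18, median 0.27, adjusted p = 0.000158), with the peptide transporter Tap1 (0.65 ± 0.32), and interferon-gamma response genes (24 of 26, median 0.27, adjusted p = 0.00017), with Irf8 (0.58 ± 0.23). All 15 glucocorticoid-responsive genes were lower (median -0.50, adjusted p = 0.000582, and adjusted p = 0.780 with an estimated correlation). Members included Tsc22d3 (-0.79 ± 0.34) and Per1 (-0.64 ± 0.38). Cardiac muscle genes were lower (10 of 14, median -0.17, adjusted p = 0.0158, and adjusted p = 0.780 with an estimated correlation), with the calcium pump regulator Pln (-0.43 ± 0.11). Cholesterol synthesis genes were higher (14 of 18, median 0.16, adjusted p = 0.0185, and adjusted p = 0.801 with an estimated correlation), with Mvd (0.30 ± 0.14). Besides Ighg1 none of these members passed adjusted over the list alone. Neutrophil markers (13 tested, median -0.05, adjusted p = 0.844), dendritic cell markers (9 tested, median 0.20, adjusted p = 0.101) and lung epithelium genes (17 tested, median -0.31, adjusted p = 0.0707) were not called.

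Many of these lung calls depended on 1 library. Cytotoxic genes lost the call (adjusted p = 0.123 without IgG replicate 2, 0.150 without IgG replicate 3). Interferon-gamma response lost the call (0.347, 0.0818 and 0.209 without IgG replicates 2 and 3 and ICB replicate 3). MHC class I lost the call (0.121 without IgG replicate 3). MHC class II lost the call (0.123 without IgG replicate 2). B and plasma cells lost the call (0.123, 0.278 and 0.144 without IgG replicates 2 and 3 and ICB replicate 2). NK cells lost the call (0.331 and 0.185 without IgG replicates 2 and 3). Glucocorticoid-responsive genes lost the call (0.344 without IgG replicate 2, 0.106 without ICB replicate 3). Cardiac genes lost the call (0.544 without IgG replicate 3, 0.0886 without ICB replicate 1). Cholesterol synthesis lost the call (0.955 in the opposite direction without IgG replicate 2, 0.667 without ICB replicate 3). T cell markers kept the call, but their difference in mean list value fell from 0.41 to 0.25 without IgG replicate 2. Of the called lung lists, the mean value per library separated the groups only for checkpoint, macrophage and cell cycle genes. The number of lists called was 7 without IgG replicate 2 and 23 without IgG replicate 1. The TPM scale moved the median over all lung genes from -0.01 to 0.20, and on that scale the called lung lists kept their directions. Erythroid (-2.04) and glucocorticoid-responsive genes (-0.45) changed little in size, and other lists changed more. The medians were then 0.74 for T cell markers, 0.98 for cytotoxic genes, 0.67 for the cell cycle and -0.02 for cardiac genes.

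No single gene passed in the lung with limma (0 of 12747 tested). There 555 had an unadjusted p under 0.05 against 637 by chance, and limma-voom on the recovered reads called 0. In 1 fit of all 36 libraries 55 were called. Among the smallest p-values upward were those of Cd5l, a secreted macrophage protein, which stood at 0.740 ± 0.122 FPKM in IgG and 4.54 ± 1.50 FPKM in ICB (1.63 ± 0.21), Kcnab2 (0.79 ± 0.14), the phosphatase Dusp5 (0.96 ± 0.17) and Cyfip2 (0.81 ± 0.15). Downward they belonged to Mir703 (-2.11 ± 0.25), a microRNA gene inside Cfap299 on the opposite strand, Polr2k (-0.70 ± 0.16), Pla2g1b (-0.71 ± 0.17), the mitochondrial tRNA mt-Tn (-1.07 ± 0.26) and Cox6a2 (-0.74 ± 0.19). Cd274 had a difference of 0.66 ± 0.31 and Cd8a of 0.36 ± 0.24. Pdcd1, Ctla4, Foxp3 and Cxcl9 lay under the filter. The groups did not overlap for 8.65% of the genes, where chance gives 10%.

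In the liver, transcripts of macrophages, MHC class II and inflammatory cytokines were higher with ICB, and genes of fatty acid oxidation were lower. Of 17 macrophage and monocyte markers 16 were higher (median 0.99, camera adjusted p = 1.71e-12, and adjusted p = 0.353 with an estimated correlation). Among them were the lysozyme Lyz2 (2.16 ± 0.51) and Adgre1, which encodes F4/80 (1.06 ± 0.28), and 2 passed adjusted over the list alone. The rise was in 2 of the 3 ICB livers: the mean list value was 5.81 and 6.15 in ICB replicates 1 and 3, but 4.48 in ICB replicate 2, within the 4.30 to 4.67 of IgG, and without ICB replicate 3 the difference fell from 1.00 to 0.66. All 6 MHC class II genes were higher (median 0.95, adjusted p = 5.5e-08, and adjusted p = 0.312 with an estimated correlation), 4 of them passing adjusted over the list alone, with Cd74 at 1.24 ± 0.46 and H2-DMa at 0.83 ± 0.25. All 7 tested inflammatory cytokines and chemokines were higher (median 0.90, adjusted p = 1.3e-06, and adjusted p = 0.312 with an estimated correlation), and Il1b (1.10 ± 0.18), Cxcl16 (1.24 ± 0.38) and Il18 (0.90 ± 0.30) passed adjusted over the list alone. For this list too the mean value of 1 ICB library lay within those of IgG. Il1b was low, at 0.7795 FPKM in IgG and 2.795 FPKM in ICB on average. All 23 genes of fatty acid oxidation and targets of PPAR-alpha were lower (median -0.38, adjusted p = 1.47e-09, and adjusted p = 0.312 with an estimated correlation). Leading were the pantetheinase Vnn1 (-1.59 ± 0.29), the 1 member that passed adjusted over the list alone, and the fatty acid hydroxylases Cyp4a10 (-2.29 ± 0.72) and Cyp4a14 (-2.76 ± 0.89).

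B and plasma cell markers (5 of 5, median 0.36, camera adjusted p = 4.83e-05) and immediate early genes (12 of 14, median 0.30, adjusted p = 0.0036) were also higher in the ICB livers. Unfolded protein and heat shock genes were lower (13 of 17, median -0.22, adjusted p = 0.00424). These lists each had an adjusted p = 0.312 with an estimated correlation. Their members included the immunoglobulin genes Ighg1 (1.80 ± 0.28) and Igkc (1.46 ± 0.36), both passing adjusted over the list alone, Nr4a1 (0.73 ± 0.24), and Hspa5, the main chaperone of the endoplasmic reticulum (-0.74 ± 0.28). Ighg1 stood at 0.359 FPKM in IgG and 3.92 FPKM in ICB on average. Interferon-gamma response genes (19 of 25, median 0.31, adjusted p = 6.07e-05, and adjusted p = 0.747 with an estimated correlation) included Gbp2 (0.71 ± 0.21). Cell cycle genes (8 of 8, median 0.38, adjusted p = 0.0135, and adjusted p = 0.747 with an estimated correlation) included Pcna (0.37 ± 0.20) and Mcm5 (0.66 ± 0.57). MHC class I genes (15 of 18, median 0.17, adjusted p = 0.0211, and adjusted p = 0.797 with an estimated correlation), activated endothelium genes (7 of 8, median 0.26, adjusted p = 0.0216, and adjusted p = 0.446 with an estimated correlation) and genes of p53 targets and apoptosis (14 of 18, median 0.17, adjusted p = 0.0216, and adjusted p = 0.660 with an estimated correlation) were higher. Fatty acid synthesis genes were lower (14 of 15, median -0.34, adjusted p = 0.0294, and adjusted p = 0.797 with an estimated correlation). Members included Fasn at -0.51 ± 0.33. Besides the 2 immunoglobulin genes none of these members passed adjusted over the list alone. Erythroid genes (7 tested, median -0.15, adjusted p = 0.640), hepatocyte function genes (20 tested, median -0.07, adjusted p = 0.874), acute phase genes (26 tested, median 0.04, adjusted p = 0.874) and drug metabolism cytochromes (19 tested, median -0.03, adjusted p = 0.640) were not called.

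Several liver calls depended on 1 library. Cell cycle lost the call (adjusted p = 0.732 in the opposite direction without ICB replicate 3, with Mcm5 then at -0.07). MHC class I lost the call (0.665 in the opposite direction without IgG replicate 1, 0.0935 and 0.205 without ICB replicates 2 and 3). Interferon-gamma response lost the call (0.495 without IgG replicate 1). Endothelium lost the call (0.143 without IgG replicate 2, 0.0963 and 0.205 without ICB replicates 1 and 3). Fatty acid synthesis lost the call (0.635 and 0.222 without IgG replicates 2 and 3, 0.921 without ICB replicate 1). Unfolded protein response lost the call (0.134 without ICB replicate 2). The p53 targets lost the call (0.0836 without IgG replicate 2, 0.402 without ICB replicate 3). MHC class II kept the call, but its difference in mean list value fell from 0.96 to 0.57 without IgG replicate 1. Of the called liver lists, the mean value per library separated the groups only for MHC class II, B and plasma cell, fatty acid oxidation and immediate early genes. No single gene passed with limma (0 of 11257 tested). There 379 had an unadjusted p under 0.05 against 563 by chance, and limma-voom on the recovered reads called 0. In 1 fit of all 36 libraries 74 were called. Without ICB replicate 2 limma called 42 genes, and without IgG replicate 1 it called 1. Upward, the smallest p-values besides Ighg1 and Il1b belonged to the lipoprotein lipase Lpl (1.57 ± 0.26, from 3.90 ± 1.20 to 13.7 ± 4.33 FPKM), Slc26a10 (1.45 ± 0.29) and Mir1943 (1.09 ± 0.15), a microRNA gene inside Tmem184b that was listed at 0 in all 3 IgG libraries. Downward, besides Vnn1, they belonged to Creld2, an endoplasmic reticulum stress gene (-1.19 ± 0.28), Acot3 (-0.96 ± 0.24), Hapln4 (-0.77 ± 0.20) and Smpd3 (-0.85 ± 0.22). Cd274 had a difference of 0.69 ± 0.26 and Cxcl9 of 0.71 ± 0.44. Pdcd1, Ctla4, Cd8a and Foxp3 lay under the filter. The groups did not overlap for 6.84% of the genes, where chance gives 10%.

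In skeletal muscle, extracellular matrix, macrophage and MHC class II genes were higher with ICB, and adipocyte and erythroid genes were lower. Of 22 extracellular matrix genes 19 were higher (median 0.55, camera adjusted p = 3.59e-10, and adjusted p = 0.344 with an estimated correlation). Of them 12 passed adjusted over the list alone, among them the fibrillar collagens Col3a1 (1.50 ± 0.24, from 11.5 ± 4.26 to 33.4 ± 3.29 FPKM), Col1a1 (1.39 ± 0.30) and Col1a2 (1.08 ± 0.26) and Col5a2 (0.64 ± 0.13). Macrophage and monocyte markers were higher (14 of 15, median 0.77, adjusted p = 9.84e-07, and adjusted p = 0.639 with an estimated correlation). Members included Csf1r (0.87 ± 0.24) and Adgre1 (1.19 ± 0.36), though Chil3 ran the other way (-0.72 ± 0.26). All 6 MHC class II genes were higher and passed adjusted over the list alone (median 0.91, adjusted p = 1.47e-06, and adjusted p = 0.528 with an estimated correlation). Members included Cd74 at 1.12 ± 0.34. Erythroid genes were lower (6 of 7, median -1.17, adjusted p = 1.47e-06, and adjusted p = 0.528 with an estimated correlation), 6 passing adjusted over the list alone, with Hba-a2 at -2.13 ± 0.48. Adipocyte genes were lower as well (11 of 12, median -0.91, adjusted p = 1.59e-08, and adjusted p = 0.528 with an estimated correlation). Members included the lipid droplet genes Cidec (-1.41 ± 0.38) and Plin1 (-0.96 ± 0.32), so that lower fat transcripts stood beside higher macrophage and matrix transcripts. The difference in mean adipocyte value, -0.83, fell to -0.44 without IgG replicate 3. The rise of macrophage and MHC class II genes was in 2 of the 3 ICB libraries. In ICB replicate 1 the mean values were 3.06 and 4.22, within the 2.64 to 3.35 and 3.67 to 4.37 of IgG. This library has the same number in its sample title as kidney and liver ICB replicate 2, where these mean values were also the lowest of ICB.

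Interferon-gamma response genes (22 of 22 higher, median 0.41, camera adjusted p = 4.67e-05, and adjusted p = 0.722 with an estimated correlation), with Gbp7 (0.58 ± 0.22), were called in muscle. MHC class I genes (17 of 18 higher, median 0.23, adjusted p = 0.00308, and adjusted p = 0.722 with an estimated correlation), with H2-Q4 (0.60 ± 0.27), were called too. Unfolded protein and heat shock genes were lower (15 of 18, median -0.28, adjusted p = 0.00112, and adjusted p = 0.528 with an estimated correlation), with the small heat shock protein Hspb1 (-1.04 ± 0.42). Glucocorticoid-responsive genes were lower as well (14 of 15, median -0.54, adjusted p = 0.00167, and adjusted p = 0.722 with an estimated correlation), with the metallothionein Mt1 (-1.38 ± 0.68). Neither these lists nor adipocyte or macrophage genes had a member passing adjusted over the list alone. Skeletal muscle genes (17 tested, median -0.02, adjusted p = 0.505) and muscle atrophy and regeneration genes (13 tested, median -0.47, adjusted p = 0.0602) were not called. Some calls depended on 1 library. Glucocorticoid-responsive genes lost the call (adjusted p = 0.944 in the opposite direction without IgG replicate 2). Interferon-gamma response lost the call (0.250 without IgG replicate 2, 0.124 without ICB replicate 3). MHC class I lost the call (0.0567, 0.257 and 0.448 without IgG replicates 1 and 2 and ICB replicate 3). Muscle IgG replicate 2 has the same number in its sample title as lung IgG replicate 2 and liver IgG replicate 1. Without those libraries the interferon-gamma call was lost in lung and liver, the glucocorticoid call in lung and the MHC class I call in liver. These losses may thus not be separate, though other libraries also removed some of these calls. Erythroid genes kept the call, but their difference in mean list value fell from -1.12 to -0.74 without ICB replicate 3. Of the called muscle lists, the mean value per library separated the groups only for extracellular matrix, erythroid and adipocyte genes. In addition, 15 lists were called without ICB replicate 1.

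No single gene passed in muscle with limma (0 of 11410 tested). There 608 had an unadjusted p under 0.05 against 570 by chance, and limma-voom on the recovered reads called 0. In 1 fit of all 36 libraries 91 were called. Besides the collagens, the smallest p-values upward belonged to the dendritic cell gene Cd83 (1.04 ± 0.19), Gfra2 (0.70 ± 0.14) and Ndufb4c (1.08 ± 0.22), which is annotated as a processed pseudogene. Cd83 lay near the filter, at 0.229 FPKM in IgG and 1.51 FPKM in ICB on average. Downward they belonged to Ctxn3 (-1.22 ± 0.22), Mir8091 (-1.71 ± 0.38), the stretch-responsive gene Ankrd2 (-1.35 ± 0.30, from 971 ± 355 to 367 ± 72.9 FPKM), Hba-a2 and Chchd6 (-0.78 ± 0.18). Cd274 had a difference of 0.54 ± 0.23. Pdcd1, Ctla4, Cd8a, Foxp3 and Cxcl9 lay under the filter. The groups did not overlap for 11.6% of the genes, where chance gives 10%.

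In the heart, type I interferon response genes and erythroid genes were lower with ICB and MHC class II genes were higher. All 22 tested type I interferon response genes were lower (median -0.35, camera adjusted p = 2.91e-13, and adjusted p = 0.582 with an estimated correlation). Among them were Ifit2 (-0.49 ± 0.11), Ifit1 (-0.60 ± 0.16) and the RNA sensor Ifih1 (-0.31 ± 0.09). All 7 erythroid genes were lower (median -1.41, adjusted p = 2.48e-06, and adjusted p = 0.582 with an estimated correlation), with Hba-a2 at -1.68 ± 0.56. The size rested on 1 library: the mean list value was 7.32 in IgG replicate 1, 5.20 and 5.21 in the other IgG libraries and 4.41 to 4.77 in ICB, and the difference of -1.27 fell to -0.56 without that library. All 6 MHC class II genes were higher (median 0.49, adjusted p = 0.000357, and adjusted p = 0.582 with an estimated correlation), with H2-Aa at 0.49 ± 0.18. This rise was in 2 of the 3 ICB hearts: the mean list value was 3.83 and 3.77 in ICB replicates 1 and 2, but 3.09 in ICB replicate 3, under the 3.11 to 3.15 of IgG. Unfolded protein and heat shock genes were called lower (adjusted p = 0.0133, and adjusted p = 0.582 with an estimated correlation) with a mean of -0.17 but a median of 0.00 (8 of 17 members lower), and on the TPM scale the median was 0.08. Of these genes Hspa5 (-0.63 ± 0.12), Dnajb9 (-0.47 ± 0.12) and Pdia4 (-0.55 ± 0.15), which act in the endoplasmic reticulum, passed adjusted over the list alone. Interferon-gamma response genes were lower (16 of 22, median -0.09, adjusted p = 0.0325, and adjusted p = 0.935 with an estimated correlation), with Gbp3 (-0.47 ± 0.14), but on the TPM scale their median was -0.00. Immediate early genes (13 of 15, median 0.18, adjusted p = 0.0133, and adjusted p = 0.674 with an estimated correlation), with Jun (0.36 ± 0.14), and glucocorticoid-responsive genes (12 of 14, median 0.21, adjusted p = 0.0325, and adjusted p = 0.674 with an estimated correlation), with Zbtb16 (0.81 ± 0.28), were higher. Apart from the 3 endoplasmic reticulum genes, no member of the called heart lists passed adjusted over the list alone.

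Macrophage and monocyte markers (15 tested, median 0.15, camera adjusted p = 0.389) and cardiac muscle and stress genes (17 tested, median 0.01, adjusted p = 0.742) were not called in heart. Some calls depended on 1 library. Interferon-gamma response lost the call (adjusted p = 0.407, 0.302 and 0.501 without IgG replicates 1 and 2 and ICB replicate 3). Glucocorticoid-responsive genes lost the call (0.425 and 0.553 without IgG replicate 2 and ICB replicate 3). Immediate early genes lost the call (0.145, 0.0836, 0.191 and 0.116 without IgG replicates 1 and 3 and ICB replicates 1 and 3). Unfolded protein response lost the call (0.154 without ICB replicate 2). Of the called heart lists, the mean value per library separated the groups only for erythroid and unfolded protein genes. No single gene passed with limma (0 of 11476 tested). There 521 had an unadjusted p under 0.05 against 574 by chance, and limma-voom on the recovered reads called 0. In 1 fit of all 36 libraries 3 were called, and 2 were called without ICB replicate 3. The smallest p-values downward belonged to Manf, a secreted protein of the endoplasmic reticulum stress response (-1.07 ± 0.17, from 27.2 ± 2.43 to 12.7 ± 3.24 FPKM), Lypla1 (-0.54 ± 0.09), Pdia3 (-0.51 ± 0.09), the mitochondrial tRNA mt-Tp (-2.14 ± 0.39) and Hspa5. Among the smallest p-values upward were those of Cdkl1 (0.44 ± 0.09), Lgals2 (0.75 ± 0.16), Ninj1 (0.45 ± 0.10) and Dhrs3 (0.32 ± 0.07). Cd274 had a difference of -0.10 ± 0.14 (0.00 without IgG replicate 2). Pdcd1, Ctla4, Cd8a, Foxp3 and Cxcl9 lay under the filter. The groups did not overlap for 9.76% of the genes, where chance gives 10%.

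The second question was which genes moved with ICB across the 5 organs outside the tumor. On the average of kidney, lung, liver, muscle and heart, macrophage and MHC class II genes were higher, and erythroid genes and genes of the unfolded protein and heat shock response were lower. Itgb2, the integrin chain shared by leukocytes (chromosome 10, 77530252 to 77565708), was higher by 0.84 ± 0.14 on the log2 scale (SE, 3 ICB and 3 IgG libraries in each organ, adjusted p = 0.00827). Nckap1l, a regulator of actin in blood cells (chromosome 15, 103453794 to 103498810), was higher by 0.62 ± 0.10 (adjusted p = 0.00827). Each was higher in 5 of 5 organs. Limma called 23 of 8924 genes, 19 higher and 4 lower, and limma-voom on the recovered reads called 21. The next genes upward included the TNF receptor gene Tnfrsf1b (0.47 ± 0.09), the lipid transfer gene Pltp (0.59 ± 0.11), the fungal glucan receptor Clec7a (0.60 ± 0.12) and Mpeg1 (0.68 ± 0.13), each with an adjusted p = 0.0176, together with Elf4, Stk10, Plekho2 and Fam49a (0.29 to 0.48). Among the genes that fell were Tfg (-0.23 ± 0.05, adjusted p = 0.0176), the hemoglobin gene Hba-a2 (-1.69 ± 0.35, adjusted p = 0.0227) and Creld2 (-0.46 ± 0.10, adjusted p = 0.0281). Ltv1, Alas2, Hspa5, Isg20, Hbb-bt, Zranb2 and Scp2 did not pass (adjusted p = 0.0568 to 0.103).

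Camera, whose use on the organ average was chosen after the data were seen, called 10 of the 22 lists testable there, 7 higher and 3 lower, and 5 were also called with an estimated correlation. Those were macrophage and monocyte markers (median 0.66, adjusted p = 3.17e-17, and adjusted p = 0.0211 with an estimated correlation) and MHC class II genes (median 0.71, adjusted p = 1.7e-14, and adjusted p = 0.0211 with an estimated correlation). They were also extracellular matrix genes (median 0.21, adjusted p = 3.44e-06, and adjusted p = 0.0461 with an estimated correlation), erythroid genes (median -1.26, adjusted p = 4.21e-12, and adjusted p = 0.029 with an estimated correlation) and unfolded protein and heat shock genes (median -0.19, adjusted p = 1.54e-05, and adjusted p = 0.029 with an estimated correlation). The call was lost with an estimated correlation for interferon-gamma response (median 0.18, adjusted p = 0.244 with an estimated correlation), MHC class I (0.18, adjusted p = 0.198 with an estimated correlation), immediate early genes (0.13, adjusted p = 0.0515 with an estimated correlation), activated endothelium (0.14, adjusted p = 0.151 with an estimated correlation) and fatty acid oxidation (-0.12, adjusted p = 0.244 with an estimated correlation). The number in the sample title recurs between organs, and the labels do not state whether it marks the mouse. With that number as a replicate block 2 of the 23 genes, Itgb2 and Nckap1l (blocked adjusted p = 0.0209 each), were called. Of 100 drawn splits of the 10 numbers, which keep a number's libraries together, 19 called at least 23 genes, with 1009 the highest count. In an exact permutation test over the 10 numbers (252 splits, two-sided, chosen after the data were seen), the differences were 0.78 for MHC class II (p = 0.00794), 0.63 for macrophages (p = 0.0238) and -1.10 for erythroid genes (p = 0.0397), each with an adjusted p = 0.150 over the 22 lists. With the number as a block, fry (also chosen after the data were seen) called 4 of the 5 lists but not extracellular matrix genes (blocked adjusted p = 0.109). The gene count also depended on single organs, with 11 genes without kidney, 10 without lung, 1 without liver, 5 without muscle and 66 without heart. It depended on single libraries too, with 15 genes without muscle ICB replicate 3, 119 without liver ICB replicate 2 and 37 to 52 without any of 5 others (lung IgG replicates 1 and 3, liver IgG replicate 2, muscle IgG replicate 3, muscle ICB replicate 1). Kidney ICB replicate 2, liver ICB replicate 2, muscle ICB replicate 1 and heart ICB replicate 1 carry the same title number. Each had the lowest macrophage value of its organ's ICB libraries (2.35, 4.48, 3.06 and 3.28), so these low values may not be separate. In heart its MHC class II value, 3.83, was not the lowest. The lowest macrophage score of an ICB number, -0.29, lay within the -0.38 to -0.18 of the IgG numbers. Of the 10 list calls, 2 were lost without liver, and all 10 were kept without any other organ (preset correlation).

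**Figure D3:**
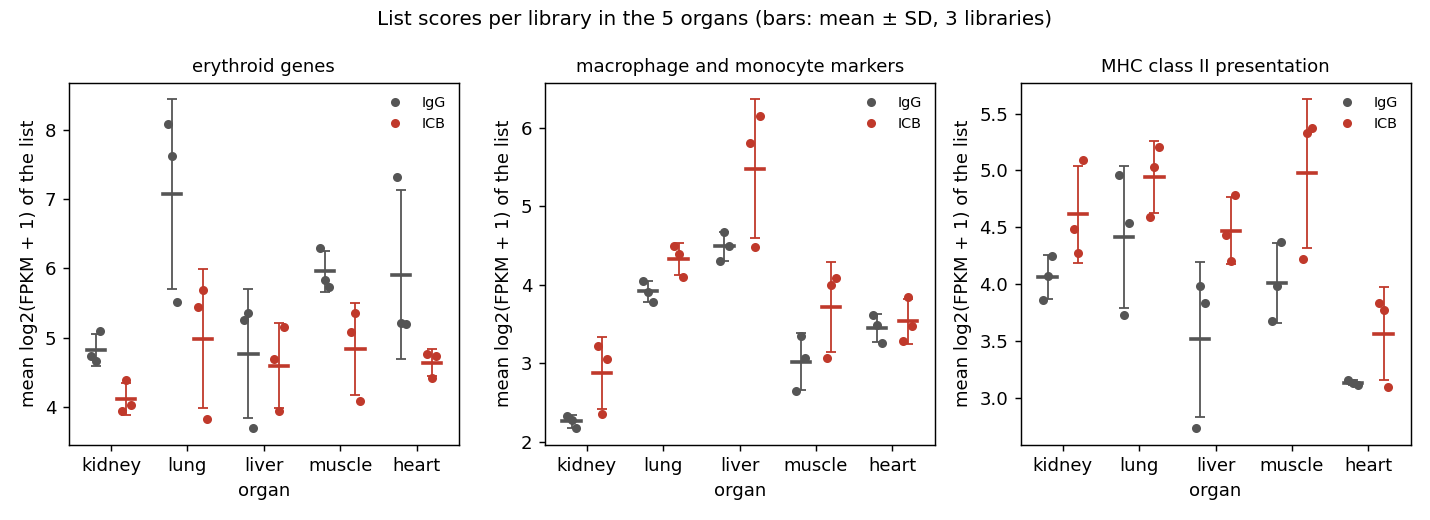
Mean log2(FPKM + 1) over the tested members of 3 gene lists (vertical axes) per library in the 5 organs (horizontal axes), IgG in gray and ICB in red, with bars for the mean ± SD of 3 libraries. Erythroid values separate the groups in kidney, muscle and heart, macrophage values separate them in kidney and lung, and MHC class II values separate them in kidney and liver. In kidney the macrophage and MHC class II values of ICB replicate 2 (2.35 and 4.27) lie just above the highest IgG values (2.33 and 4.25).

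The third question was whether the ICB effect differed between tissues. Tested directly, with the tumor against the mean of the 5 organs, 38 of 16123 genes differed (limma, 21 with a positive and 17 with a negative signed difference, tumor minus organs). The difference was positive for the keratin Krt16 (0.88 ± 0.11, SE), the carbonic anhydrase Car6 (0.96 ± 0.13), the hyaluronan synthase Has2 (1.62 ± 0.23), the matrix protein Fbln2 (1.32 ± 0.21), the imprinted gene Peg10 (1.22 ± 0.21) and Ifit1bl1 (1.13 ± 0.20). It was negative for the transporter Slc47a1 (-1.45 ± 0.25), Syt13 (-1.12 ± 0.19), Dppa4 (-1.02 ± 0.19) and Mfge8, which aids the uptake of dying cells (-0.87 ± 0.17). The largest adjusted p among these genes was 0.013 (Mfge8). With a pseudocount of 0.1 the calls of Has2, Fbln2, Peg10, Ifit1bl1, Syt13 and Dppa4 were lost. Only 4 of the 38 genes passed the expression filter in all 6 tissues, and the others took part of their spread from tissues in which they lay under it. Among the 8485 genes that passed it in all 6 tissues limma called 0, where the whole set held 1021 genes at an unadjusted p under 0.05. A joint test over the 6 tissues called 14 genes, and 5 with a pseudocount of 0.1, where the tumor contrast called 18. Without single tumor libraries the tumor contrast called 80, 23 and 287 genes (IgG replicates 1, 2 and 3) and 90 and 24 genes (ICB replicates 1 and 3).

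Among the lists, the unfolded protein and heat shock response had a positive difference, tumor minus organs, with a rise in the tumor and a fall in the organs (median difference 0.40, camera adjusted p = 2.04e-07), and this call held with an estimated correlation (adjusted p = 0.0406). The type I interferon response (0.52, adjusted p = 2.04e-07, and adjusted p = 0.757 with an estimated correlation) and interferon-gamma response (0.24, adjusted p = 0.00105, and adjusted p = 0.887 with an estimated correlation) also had positive differences. Cytotoxic effector genes (-0.64, adjusted p = 1.83e-09, and adjusted p = 0.310 with an estimated correlation) and NK cell markers (-0.49, adjusted p = 3.33e-07, and adjusted p = 0.310 with an estimated correlation) had negative ones. The cytotoxic and NK lists share Gzma, Prf1 and Eomes. Between tumor and heart the type I interferon response differed by a median of 0.92 (adjusted p = 7.9e-15, and adjusted p = 0.575 with an estimated correlation), higher in the tumor and lower in the heart. Between pairs of tissues limma called 34 genes for tumor and lung, 16 for tumor and muscle, 11 for tumor and liver, 10 for tumor and heart and 8 for tumor and kidney. It called 0 for kidney and lung, kidney and liver, and lung and liver, where 371, 714 and 1117 genes had an unadjusted p under 0.05.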

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

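The tests of blood, scaling, single libraries, fat, muscle tissue, T cells and NK cells were chosen only after the results were seen, while the splits of the samples were planned.

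A test of the difference itself singled out genes whose ICB effect differed between tissues. These were 8 genes for tumor and kidney, 34 for tumor and lung, 11 for tumor and liver, 16 for tumor and muscle, 10 for tumor and heart, 5 for kidney and muscle, 1 for kidney and heart, 10 for lung and muscle, 6 for lung and heart, 5 for liver and muscle, 1 for liver and heart and 7 for muscle and heart. The tumor against the 5 organs gave 38 genes and the joint test 14. Of 100 drawn splits 41 gave at least 38 genes (highest 364) and 83 gave at least 14 (highest 624), so chance cannot be excluded for either count, and splits with several times the real count point to a structure of the samples. The effects of the genes with the smallest p-values, tumor minus organs, were 0.88 for Krt16, 0.96 for Car6, 1.62 for Has2, 1.03 for Tex19.1, 0.96 for Fam131b, 1.32 for Fbln2, 1.22 for Peg10, 0.40 for Tmem74, 1.13 for Ifit1bl1 and 0.55 for Ephb2 upward. Downward they were -0.89 for Nkx6-3, -1.12 for Syt13, -1.45 for Slc47a1, -0.36 for Prss42, -0.41 for Luzp4, -1.02 for Dppa4, -0.78 for Zbtb7c, -0.87 for Mfge8, -0.72 for Best1 and -0.96 for Qprt. With a pseudocount of 0.1 the calls of 13 of these 20 genes were lost. Lists with a positive signed difference, tumor minus organs, were the type I interferon response (median 0.52, and 0.92 against heart alone), interferon-gamma response (0.24), hypoxia (0.24), unfolded protein response (0.40), erythroid (0.82, lower in the organs), adipocyte (0.28), skeletal muscle (1.24) and muscle atrophy genes (0.19), and lists with a negative one were cytotoxic (-0.64), checkpoint (-0.22), MHC class II (-0.37) and NK cell genes (-0.49). Of these lists only the unfolded protein response was called with an estimated correlation (adjusted p = 0.0406), and the others had adjusted p = 0.310 to 0.887. The skeletal muscle list rested in the tumor on ICB replicate 2 (adjusted p = 0.469 there without it).

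Within tissues, 10 splits cannot give a share under 0.05. The real split and the highest other gave 0 and 1 genes in tumor, 2 and 0 in kidney, 0 and 1 in lung, 0 and 1 in liver, 0 and 0 in muscle and 0 and 0 in heart. For lists they gave 12 and 17 in tumor (4 splits with as many, the real one included), 14 and 19 in kidney (2), 14 and 21 in lung (7), 13 and 14 in liver (2), 9 and 16 in muscle (7) and 7 and 13 in heart (9). On the organ average, 3 of 100 drawn splits, the real one included, gave at least 23 genes (highest 365). That share holds only for independent libraries, and libraries of the same title number correlated (median r 0.15), so chance is not excluded. For lists, 19 of the splits gave at least 10 (highest 15), which does not exclude chance either. When splits kept the libraries of a title number together, 19 of 100 gave at least 23 genes (highest 1009) and 44 gave at least 10 lists (highest 15), so variation shared by libraries of a number is not excluded, and the high counts point to such a structure.

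Erythroid genes were lower on the organ average. A change to the TPM scale is too small to be the cause. It moved the median over all lung genes from -0.01 to 0.20 and left an erythroid median of -1.18, so it could hardly have removed the difference. The camera call was kept without each organ library (largest adjusted p = 2.58e-09 over 30 fits without 1 organ library, with the preset correlation). Kept calls decide little here too, since this test called up to 15 lists on the organ average in other drawn splits. The size depended on single libraries, as the heart difference of -1.27 fell to -0.56 without IgG replicate 1. In lung, muscle and heart the highest erythroid value was that of IgG replicate 1 (8.09, 6.30 and 7.32). These libraries carry the same title number, which leaving out 1 library at a time does not test. Less blood left in the ICB organs cannot be told apart from fewer erythroid transcripts in blood, since S100a8 and S100a9, abundant in neutrophils, had a mean difference of -0.23 (95% interval -1.14 to 0.67). In lung, S100a8 stood at 749.5, 603.3 and 36.93 FPKM in IgG replicates 1, 2 and 3. It stood at 336.4, 343.5 and 91.86 FPKM in the ICB lungs. A biological effect of ICB on red cell precursors stays open and untested.

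Macrophage and MHC class II genes were higher on the organ average. More blood in the ICB organs would raise erythroid genes, which had a difference of -1.10 per title number. A lower share of each organ's main cells would raise both groups, which lay apart by 1.73. That gap cannot decide the question, because less blood left in the ICB organs, which stays open, would lower erythroid genes by itself. Fat on the muscle is argued against by an adipocyte median of -0.91 there, where the score difference of -0.83 fell to -0.44 without IgG replicate 3 but the call was kept. Fat on the kidney cannot be told apart from the ICB effect in that organ (adipocyte median 0.77), as too few libraries have equal fat content. More macrophages, or more expression per cell, may underlie the rest as a hypothesis.

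In the tumor, interferon genes were higher and cytotoxic genes lower. With the preset correlation both lists kept their calls without ICB replicate 2, which held muscle transcripts (larger adjusted p = 0.0118). They also kept them without each other library (largest adjusted p = 0.0211, cytotoxic genes without IgG replicate 3). Kept calls decide little, since this test called up to 17 tumor lists in other splits. The cytotoxic difference in mean list value fell from -0.57 to -0.38 without ICB replicate 2, so part of it rested on that library. The type I interferon difference fell from 0.59 to 0.41 without IgG replicate 1. Muscle tissue in ICB replicate 2 is argued against only as the whole cause. Fewer T cells cannot be told apart from lower expression per cell, since 6 of the 8 tested markers lay under 5 FPKM in IgG (score difference 0.07). The same holds for fewer NK cells (median -0.39 over 4 markers, among them the cytotoxic genes Gzma and Prf1). An ICB effect on interferon signaling stays a hypothesis.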

How the results depend on the processing

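Limma-voom, the filter in all 6 tissues, single-library fits of the 36-library contrasts, and the list test on the organ average with its estimated correlation and fry were chosen only after the data were seen.

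Many settings moved a count, and unless stated the cause was not tested. In 1 fit of all 36 libraries, which shares the spread between tissues, limma called 69 genes in tumor, 12 in kidney, 55 in lung, 74 in liver, 91 in muscle and 3 in heart. Array weights called 2 genes in tumor, 3 in kidney and 1 in muscle. Kidney fell to 1 gene with no filter, with quantile normalization and with limma-voom, and liver gave 1 with no filter. With an estimated correlation camera called 0 lists in each of the 6 tissues, where fry called 1 in tumor and 0 elsewhere. Of the 69 list calls in single tissues, 5 were lost with quantile normalization and 1 with median-of-ratios scaling. The tumor then had 9 and 11 lists, where the main setting gave 12. The tumor against the organs gave 48 genes with the replicate block, 18 with a pseudocount of 0.1 and 0 with the filter in all 6 tissues, which tests fewer genes, and the joint test gave 27 with the replicate block, 5 with a pseudocount of 0.1 and 0 with that filter. The organ average gave 2 genes with the replicate block, 33 with a pseudocount of 0.1, 11 without kidney, 10 without lung, 1 without liver, 5 without muscle and 66 without heart. Its lists numbered 5 with an estimated correlation, 5 with fry and 4 with fry and the block. Libraries of the same title number correlated more (median r 0.15 over 56 pairs across genes, which are not independent replicates) than libraries of different numbers (median -0.04 over 214 pairs).

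Leaving out 1 library gave 0 to 6 genes in tumor, 1 to 9 in kidney, 0 to 42 in liver and 0 to 2 in heart, 7 to 23 lists in lung and 7 to 15 in muscle, and 23 to 287 genes for the tumor against the organs, 11 to 120 in the joint test and 15 to 119 for the organ average. Directions changed for Pdcd1 (-0.06 to 0.36) and Cd274 (-0.04 to 0.41) in tumor, Mcm5 (-0.07 to 1.13) and Icam1 (-0.00 to 0.54) in liver and Cd274 in heart (-0.26 to 0.00). They also changed for the hypoxia and glycolysis list in tumor (adjusted p = 1.6e-06 to 0.709) and the cholesterol synthesis list in lung (9.68e-05 to 0.955). The same held for the MHC class I presentation list in liver (2.87e-05 to 0.665), the cell cycle list in liver (2.4e-05 to 0.732) and the glucocorticoid-responsive genes list in muscle (1.12e-05 to 0.944). Depth was 19005189 to 25512980 reads per library, and whether it limited the genes under the filter was not tested.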

Other observations

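The values here were chosen only after they were seen, and none was tested. In kidney, the injury gene Havcr1 stood at 20.3 FPKM in ICB replicate 3 and at 0.293 to 0.512 FPKM in the other 5 libraries. In liver, the macrophage receptor gene Marco stood at 337 FPKM in ICB replicate 1 and 549 FPKM in ICB replicate 3, against 12.4 to 29.6 FPKM in the others, and Mki67 at 2.60 FPKM in ICB replicate 3. In muscle, the atrophy gene Trim63 stood at 3197 FPKM in IgG replicate 2. In heart, Myh7 stood at 156 FPKM in ICB replicate 3 and at 26.8 to 52.8 FPKM in the others.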
